A study of Mus musculus with 72 samples.

How the data were processed

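RNA from whole blood of 72 mice, 1 array per mouse, had been measured on 1-colour Affymetrix mouse arrays. Per the labels, blood was taken after injection into the tail vein with Candida albicans or Staphylococcus aureus or from healthy BALB/c mice labelled male, and the RNA was depleted of beta-globin transcripts, amplified and labelled with biotin. The deposited values are log2 signals per probe set, made by the authors with Affymetrix Expression Console, whose version, summarising algorithm and normalization are not given in the sources used here. They were used as deposited, since they were already on the log2 scale and at a common level: array means lay between 5.45 and 5.52, medians between 5.20 and 5.35 and interquartile ranges, called array spread, between 2.26 and 3.62. No array was an exact copy of another (highest Pearson r 0.995). Pathogen burden of the kidney, which the labels mention, was not analysed here. Files of raw probe intensities were not used here.

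Groups were taken from the labels for infection, cohort and day, and replicates were separate mice. A gene was represented by the probe set with the highest mean signal among those with 1 gene symbol. Of 22690 probe sets, 64 were controls, 20380 had 1 symbol, 691 had several and 1555 had none, which left 12393 genes, 4956 of them with more than 1 probe set. Of the probe sets with 1 symbol, 20351 matched a gene of the GRCm38 annotation by Entrez number, and 0 symbols had to be updated.

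Within each cohort, limma (version 3.58.1, R 4.3.3) fitted group means and tested contrasts with lmFit and eBayes, two-sided, and the Benjamini-Hochberg method adjusted p over all genes tested, with a threshold of 0.05. The initial candida cohort was compared with its 12 healthy mice of both days as the mean of days 1 to 4, day by day, as day 4 against day 1, and by a joint test of any difference among the days. The written design named both a pooled healthy group and 6 groups sharing 1 estimate of variance. The pooled form was used for infected against healthy mice, and 6 groups for the healthy mice of day 4 against day 1. The 6-group form was tried for the others after the data were seen and moved no count by more than 1.5 times. The validation and S. aureus cohorts were compared with their own healthy mice. A fit with cohort as an additive term gave the difference between the candida effect and the S. aureus effect. A fit of both candida cohorts gave the difference between their effects. The arrays with 2 mice in a group borrow the variance of the other groups of the fit.

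The comparisons, the alternatives, the rule for naming genes and the gene lists were fixed before the data were examined. The rule named the 10 genes with the largest change in each direction among those that passed in every infected mouse, list members that passed, and a fixed set of genes, of which Card9 was not measured. Genes named outside it are said to be chosen after their values were seen. The 28 lists covered mature and immature neutrophils, monocytes, B, T, natural killer, plasma, dendritic and erythroid cells, platelets, eosinophils with basophils and mast cells, and tissue outside blood. They also covered type I interferon, interferon gamma, MHC class II, C-type lectin receptors, Toll-like receptors with interleukin-1, interleukin-17, cytokines, STAT3, complement with Fc receptors, cell cycle, ribosome, glycolysis, oxidative phosphorylation, oxidant defence, immune suppression and handling. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. fry asks whether genes of a list move on balance one way and compares them with no other genes.

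The signature score of a mouse was the mean signal of 50 genes minus that of 50 others, the extremes of limma's statistic in the initial cohort. It was tested in the other cohorts with an exact permutation test over all arrangements of the mice. A liver score was the mean signal of the 4 genes Alb, Apoa1, Apoa2 and Ttr, and an Alb signal above 8 marked mice for an alternative. Alternatives chosen beforehand were quantile and cyclic loess scaling, the mean of all probe sets, leaving out genes below the median signal, trend and robust eBayes, array weights, a fit on all 72 mice, other sets of healthy mice, a block for the title number set, other cohort terms and leaving out each mouse in turn. Those chosen after seeing the data were liver score and array spread as covariates, leaving out mice with Alb above 8 or 1 mouse with low Xist, and the 6-group fit. The fits were tested on simulated data with known changes before use. Self-written scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision.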

Results

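Gene expression was measured in whole blood of 72 BALB/c mice, with 1 array per mouse, at the end of 1 to 4 days of infection or without infection. The mice formed 3 cohorts. In the initial candida cohort, blood came from 8, 6, 7 and 7 mice infected with Candida albicans for 1, 2, 3 and 4 days, and from 8 healthy mice of day 1 and 4 healthy mice of day 4. The validation candida cohort held 6, 8 and 4 mice infected for 1, 2 and 3 days and 2 healthy mice. The Staphylococcus aureus cohort held 2, 5 and 2 mice infected with this bacterium for 1, 2 and 3 days and 3 healthy mice. The signals of 22690 probe sets ran from 1.2 to 14.37 log2 units, and the mean signal of an array lay between 5.45 and 5.52. The number of arrays limits the precision of the values. All tests were two-sided, and a gene's effect is given in log2 units, infected minus healthy, with its standard error (SE) over the mice.

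The first comparison asked how the blood of mice with invasive candidiasis differs from that of healthy mice, in 28 infected and 12 healthy mice of the initial cohort, as the mean of the 4 days. Lcn2 (Entrez gene 16819), which encodes a siderophore-binding lipocalin of neutrophil granules, had a signal of 11.37 ± 0.52 (SD, n = 28) in infected and 7.70 ± 0.38 (SD, n = 12) in healthy mice. Its effect was 3.67 ± 0.16 (SE, adjusted p = 7.75e-21), with 28 of 28 infected mice above the healthy mean. Clec4e (Entrez gene 56619), the gene of the glycolipid receptor Mincle, rose by 3.51 ± 0.14 (SE, adjusted p = 2.01e-22) in 28 of 28 mice. Sptb (Entrez gene 20741), which encodes the beta spectrin of the red cell membrane, had an effect of -1.69 ± 0.15 (SE, adjusted p = 3.04e-12), with 0 of 28 mice above the healthy mean. Of 12393 genes tested, 2746 rose and 3628 fell at an adjusted p under 0.05, and 436 and 107 of these changed at least 2-fold.

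The other genes of largest increase, each higher in 28 of 28 mice, were the metalloreductase gene Steap4 (3.73 ± 0.20, SE), the proteoglycan gene Vcan (3.65 ± 0.17), the secreted glycoprotein gene Lrg1 (3.60 ± 0.21) and the chitinase-like gene Chil3 (3.38 ± 0.22). They were followed by Wfdc21 (3.23 ± 0.17), the interferon-induced gene Ifitm1 (3.12 ± 0.17), the neutrophil collagenase gene Mmp8 (3.11 ± 0.19) and the formyl peptide receptor gene Fpr2 (3.08 ± 0.14). Falls not shared by all infected mice could be as large, as for Alb (-2.10 ± 0.74), above the healthy mean in 6 of 28 mice. Among genes lower in 28 of 28 mice, the largest decreases were of Ilrun (-2.17 ± 0.19), a regulator of inflammatory signalling, the carnitine acetyltransferase gene Crat (-1.74 ± 0.13), Tmcc2 (-1.70 ± 0.16), Sptb, and Gsta3 (-1.60 ± 0.35), a glutathione transferase gene of liver. Then came Acyp2 (-1.55 ± 0.12), the amino acid transporter gene Slc38a5 (-1.50 ± 0.13), Suds3 (-1.46), the peroxisomal thiolase gene Acaa1b (-1.44 ± 0.37) and Ubac1 (-1.43). Probe sets of a gene gave unequal values for Steap4 (1.28 to 3.73), Vcan (0.06 to 3.65), Ilrun (-2.17 to -0.37) and Crat (-1.74 to -0.40), and opposite signs for Ahr (0.66 and -0.25) and Top2a (0.43 and -0.21). Without the 13 mice whose albumin (Alb) signal exceeded 8, of which 6 were infected and 7 healthy, 1749 genes rose and 1622 fell, 3281 of these 3371 were among the 6374 of all mice, and the effects of Gsta3 and Acaa1b were -0.22 and 0.04. The count was 4012 with the spread of each array as a covariate and 3802 with genes of lower signal left out.

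**Figure D1:**
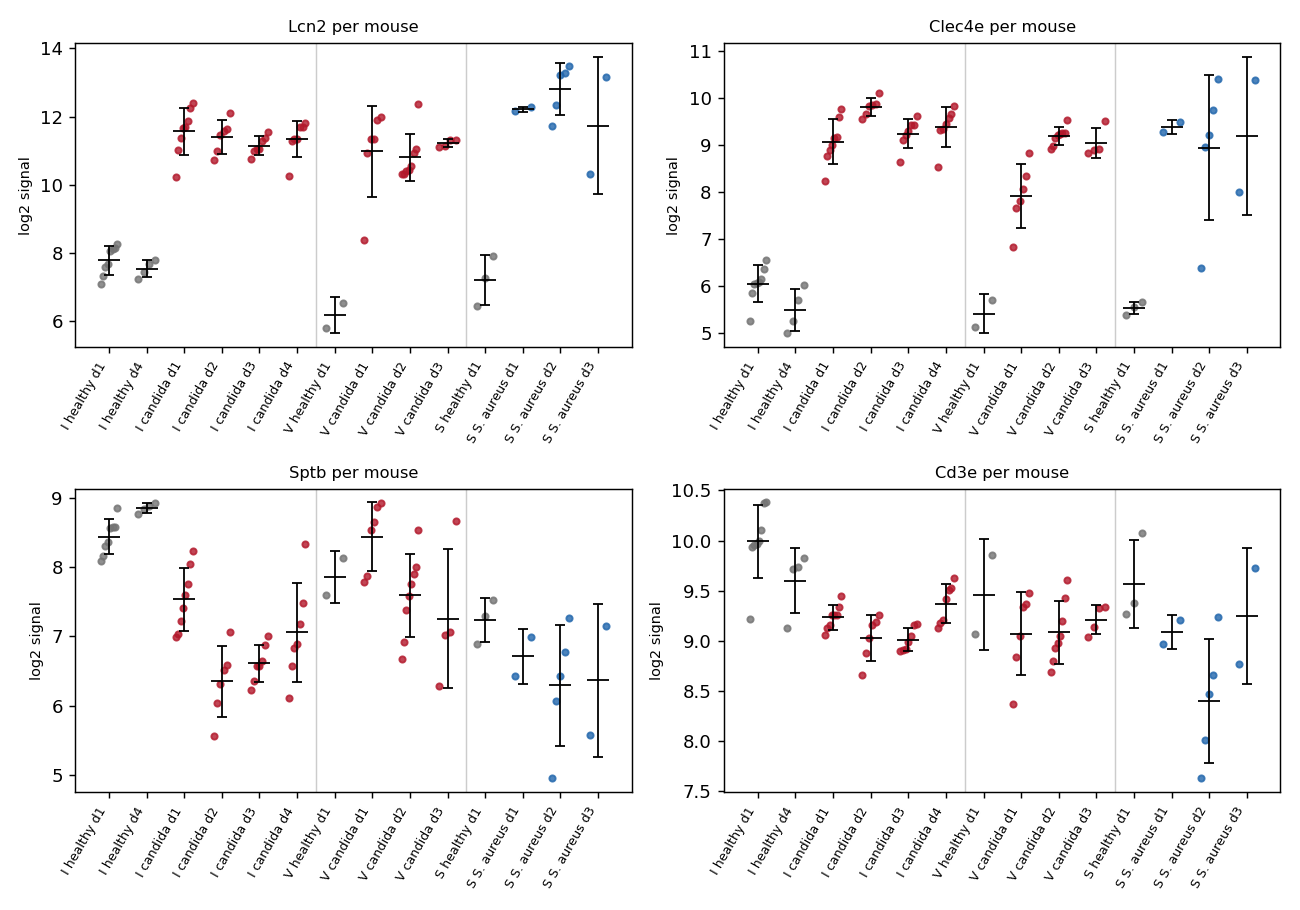
Log2 signal of Lcn2, Clec4e, Sptb and Cd3e in each of the 72 mice by group (I initial, V validation and S S. aureus cohort; grey healthy, red candida, blue S. aureus), with bars for the mean ± SD and points in order of value within a group. Lcn2 lay at 11.37 ± 0.52 in the infected and 7.70 ± 0.38 in the healthy mice of the initial cohort.

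Myeloid cell genes and the genes by which these cells recognise fungi rose as groups in the initial cohort. Of 14 measured genes of mature neutrophils 13 rose (median 1.95, camera adjusted p = 4.68e-17), among them the calprotectin genes S100a8 (1.46 ± 0.09) and S100a9 (1.78 ± 0.12) and the interleukin-1 decoy receptor gene Il1r2 (2.76 ± 0.23). The counts of members adjusted over the list alone equalled those over all genes tested unless given. Of 14 granule genes of immature neutrophils 10 rose (median 0.82, camera adjusted p = 2.72e-07), including Cd177 (2.71 ± 0.22), a surface glycoprotein gene. Of 13 monocyte genes 12 rose (median 1.16, 8.75e-10), including the growth factor receptor gene Csf1r (1.83 ± 0.11) and the chemokine receptor gene Ccr2 (1.59 ± 0.13). Of 15 genes of C-type lectin receptor signalling 14 rose (median 0.93, 5.93e-14), among them Clec7a (1.73 ± 0.14, adjusted p = 6.79e-13), which encodes the beta-glucan receptor dectin-1, and Clec4n (2.07 ± 0.11), which encodes the mannan receptor dectin-2. Of 22 genes of Toll-like receptor and interleukin-1 signalling 15 rose and 4 fell (median 0.98, camera adjusted p = 9.78e-09), with increases of Tlr2 (1.88 ± 0.12) and Il1b (1.90 ± 0.13). All 12 STAT3 response genes rose (median 1.5, 5.59e-13), including the signalling inhibitor gene Socs3 (2.63 ± 0.17). These 6 lists were the ones that passed with an estimated correlation between genes as well, at an adjusted p from 0.0226 for mature neutrophils to 0.0466 for immature neutrophil genes.

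Most T cell, B cell and erythroid genes fell, though these lists did not pass with an estimated correlation. All 17 T cell genes fell (median -0.67, camera adjusted p = 1.45e-07, adjusted p = 0.132 with an estimated correlation), among them the T cell receptor chain gene Cd3e (-0.70 ± 0.09, lower in 28 of 28 mice) and the homing receptor gene Ccr7 (-0.93 ± 0.11). Of 15 B cell genes 13 fell (median -0.45, 4e-04, adjusted p = 0.322 with an estimated correlation), including the kinase gene Blk (-0.82 ± 0.10) and the B cell receptor gene Cd79a (-0.54 ± 0.14, lower in 23 of 28 mice). Of 21 erythroid genes 19 fell (20 adjusted over the list alone, median -1.03, 1.53e-09, adjusted p = 0.0827 with an estimated correlation), with decreases of the transcription factor gene Klf1 (-1.41 ± 0.12) and of Hemgn (-1.25 ± 0.14). Of 13 platelet genes 10 rose (median 0.88, 0.00604, adjusted p = 0.499 with an estimated correlation), with effects of 1.48 ± 0.38 for the adhesion receptor gene Gp1bb and 1.24 ± 0.42 for Vwf, and 2 rose without the mice of high albumin signal. The genes for tissue outside blood included the liver genes Alb (-2.10 ± 0.74, adjusted p = 0.0168, above the healthy mean in 6 of 28 mice), Apoa2 (-1.62) and Ttr (-1.37). Of these 16 genes 7 fell (6 adjusted over the list alone, median -0.32, 0.0484, adjusted p = 0.529 with an estimated correlation), and 1 fell without the mice of high albumin signal. Of 15 natural killer and cytotoxic genes 1 fell, Eomes (-0.45), and the list did not pass (median -0.01, 0.871).

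Interferon genes went apart in the initial cohort. Of 23 genes of the type I interferon response 13 rose and 4 fell (median 0.47, camera adjusted p = 0.00141, adjusted p = 0.316 with an estimated correlation): the antiviral gene Oas2 (1.2 ± 0.13) and the receptor transporter gene Rtp4 (1.38) rose, whereas Ifit1 (-0.57 ± 0.11, adjusted p = 3.65e-05) and the regulator gene Irf7 (-0.93 ± 0.11) fell, each in 28 of 28 mice. Of 17 genes of the interferon gamma response 10 rose (median 0.35, 0.00307, adjusted p = 0.316 with an estimated correlation), including the guanylate-binding gene Gbp2 (1.54 ± 0.12). Of 14 complement and Fc receptor genes 8 rose and 2 fell (median 0.48, camera adjusted p = 0.00393, adjusted p = 0.316 with an estimated correlation). The antibody receptor genes Fcgr4 (2.11 ± 0.12) and Fcgr3 (1.72) rose. Fcer2a (-0.82) and Cr2 (-0.62), receptor genes of the B cell list, fell. Of 13 glycolysis genes 11 rose (median 0.79, 2.72e-07, adjusted p = 0.126 with an estimated correlation), including the glucose transporter gene Slc2a1 (1.08). Of 25 genes of oxidative phosphorylation 12 rose and 3 fell (median 0.24, 0.0198, adjusted p = 0.542 with an estimated correlation), with Cox5a at 0.57 and the ATP synthase gene Atp5b at -0.75 ± 0.09. Of 15 oxidant defence genes 8 rose and 5 fell (median 0.37, 0.0271, adjusted p = 0.316 with an estimated correlation), with increases of the NADPH oxidase genes Cybb (1.43) and Ncf4 (1.61). Of 18 genes that respond to handling of the sample 9 rose and 6 fell (median 0.23, 0.045, adjusted p = 0.322 with an estimated correlation), with Junb at 1.27 and the heat shock gene Hspa1b at -1.11 ± 0.31. Hspa1b lay at 4.63 ± 0.23 (SD, n = 28) in infected mice, at 4.88 ± 0.20 (SD, n = 8) in healthy mice of day 1 and at 7.45 ± 2.11 (SD, n = 4) in healthy mice of day 4, so its fall was carried by the latter. After quantile scaling the medians of the oxidative phosphorylation, interferon gamma and handling lists were 0.002, 0.14 and 0.15. With the mean of 4 liver genes as a covariate the handling list no longer passed, at an adjusted p of 0.122.

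Of the 9 other lists that did not pass in the initial cohort, several had members that changed. Of 23 cell cycle genes 8 fell and 3 rose (median -0.01, camera adjusted p = 0.565), with Mki67, a marker of dividing cells, at -1.11 ± 0.12. Of 9 plasma cell genes 4 fell and 2 rose (2 higher and 5 lower adjusted over the list alone, 0.817), with the antibody joining chain gene Jchain at -0.56 and the transcription factor gene Xbp1 at 1.11. Of 10 eosinophil, basophil and mast cell genes 4 fell and 1 rose (0.467), with Fcer1a, the IgE receptor gene, at -0.99. Of 8 dendritic cell genes 2 fell and 1 rose (0.973), with Cd209a at -0.58 and Itgax, which neutrophils and monocytes also express, at 0.93. Its median was -0.07 and the test pointed upward. Of 8 genes of MHC class II presentation 1 fell, H2-DMb2 (-0.47), and 0 passed adjusted over the list alone (median -0.21, 0.412). Of 10 genes of interleukin-17 signalling 3 rose and 2 fell (0.565), with a median of -0.08, a mean of 0.10 and Il17ra at 1.07 ± 0.14. Of 15 cytokine and chemokine genes 5 rose and 1 fell (2 higher and 0 lower adjusted over the list alone, 0.247), among them Cxcl2 (0.33) and Ccl6 (0.92). Of 13 immune suppression genes 5 rose and 1 fell (0.192), with a median of -0.02, a mean of 0.27 and Arg2 at 2.35 ± 0.17. Of 25 ribosomal protein genes 2 fell, Rpl12 (-0.41) and Rpl38 (-0.18), with a median of 0.06 (0.65). Of the genes fixed by name, Arg1 (-0.60 ± 0.50, adjusted p = 0.311) and H2-Aa (-0.20 ± 0.11, adjusted p = 0.123) did not pass.

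Each day was also compared with the 12 healthy mice of the initial cohort, to follow the response in time. The genes named for single days were chosen after their values were seen. Lcn2 stayed high, with effects of 3.86 ± 0.21, 3.71 ± 0.23, 3.45 ± 0.22 and 3.65 ± 0.22 (SE) on days 1, 2, 3 and 4. Csf1r, the macrophage growth factor receptor gene, went from 1.38 ± 0.15 to 2.73 ± 0.16, 1.82 ± 0.15 and 1.39 ± 0.15, and Sptb from -1.04 ± 0.20 to -2.22 ± 0.22, -1.96 ± 0.21 and -1.52 ± 0.21. On day 1, 944 genes rose and 999 fell, on day 2, 3448 and 4747, on day 3, 2306 and 2158, and on day 4, 2026 and 2311. A test of any difference among the 4 days called 6122 genes. On day 2 the median of all genes was -0.13 in the deposited values and -0.03 after cyclic loess scaling. With array spread as a covariate days 1 and 2 gave 3129 and 2609 genes, the reverse order, and any difference among days gave 1838, while quantile scaling gave 5319 on day 2 and 3534 for any difference. Without the mice of high albumin signal the counts were 1196, 2417 and 2466 on days 1, 3 and 4.

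Gene groups were also tested against healthy mice on each day of the initial cohort; calls on some days and not on others are not tests between days. All 13 monocyte genes rose on day 2 (median 1.97, camera adjusted p = 1.93e-09, adjusted p = 0.0784 with an estimated correlation), against 7 on day 1 (9 adjusted over the list alone), 11 on day 3 and 7 on day 4. On day 2, 11 of 17 interferon gamma genes rose and 1 fell (median 0.82, 8.01e-05, adjusted p = 0.213 with an estimated correlation), and 14 of 25 ribosomal genes rose (13 adjusted over the list alone, median 0.26, 0.0166, adjusted p = 0.656 with an estimated correlation). Of 13 platelet genes 12 rose on day 3 (median 1.36, 4.13e-05, adjusted p = 0.355 with an estimated correlation) and 6 on day 4 (10 adjusted over the list alone, median 1.04, 0.00136, adjusted p = 0.454 with an estimated correlation); for day 4 against day 1 the list had a median of 0.72 with no gene called over all genes or over the list alone (0.0218, adjusted p = 0.704 with an estimated correlation). Gp1bb rose by 2.32 ± 0.52 in 7 of 7 mice of day 3 (limma adjusted p = 0.000482) and did not pass on day 1 (0.64 ± 0.50, limma adjusted p = 0.447). Of 15 B cell genes 3 fell on day 1 (4 adjusted over the list alone), 13 on day 3 (median -0.74, 1.64e-06, adjusted p = 0.221 with an estimated correlation) and 13 on day 4 (median -0.64, 2.44e-05, adjusted p = 0.316 with an estimated correlation). Cd79a had an effect of -0.95 ± 0.19 on day 3, with 7 of 7 mice lower. The direction of the interferon gamma list on day 4, a median of 0.20 in the deposited values, was -0.02 after quantile scaling. On day 2 the medians of the interferon gamma and ribosomal lists were 0.54 and 0.17 after that scaling.

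**Figure D2:**
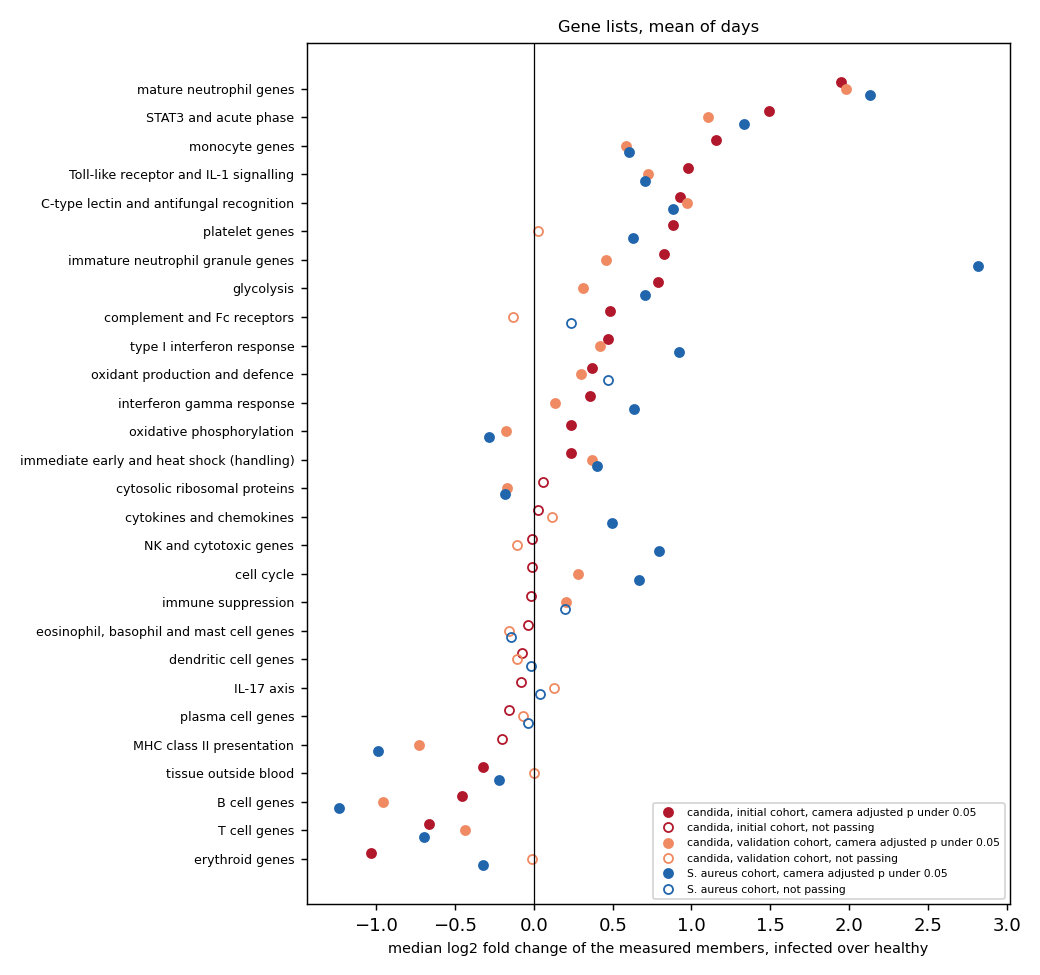
Median log2 fold change of the measured members of each of 28 gene lists, infected over healthy, in the 3 cohorts as the mean of the days; filled points mark lists with a camera adjusted p under 0.05 and open points the others. Mature neutrophil genes lay at 1.95, 1.98 and 2.13 in the initial, validation and S. aureus cohorts.

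The course from day 1 to day 4 was tested directly in 7 and 8 infected mice of the initial cohort. Clca3a1 (2.69 ± 0.45, SE, limma adjusted p = 0.000626), a gene of the chloride channel accessory family, and Tpm2 (1.99 ± 0.25, limma adjusted p = 1.05e-05), which encodes a tropomyosin, were higher on day 4 in 7 of 7 mice. The metallothionein gene Mt1 (1.90 ± 0.63), the lectin gene Clec4g (1.82 ± 0.31), known from sinusoidal endothelium, and Selenom (1.60 ± 0.29) followed. Lower on day 4 in 7 of 7 mice were Speer4a (-1.37 ± 0.31), the medium-chain fatty acid receptor gene Gpr84 (-1.33 ± 0.31, limma adjusted p = 0.00673), Carhsp1 (-1.21 ± 0.21) and Psg28 (-1.20). Other probe sets had the opposite sign for Tpm2 (-0.55), Clec4g (-0.32) and Carhsp1 (0.24). In all, 637 genes were higher and 916 lower. Of the lists 8 passed with the preset correlation and 0 with an estimated one (adjusted p = 0.704). Of 12 STAT3 response genes 1 was higher (median 0.43, 0.00464) and of 15 B cell genes 2 were lower (5 adjusted over the list alone, median -0.35, 0.0129). Lectin receptor genes (1 higher of 15, 0.31, 0.0129), glycolysis (0 of 13, 0.33, 0.0129) and platelet genes (0 of 13, 0.72, 0.0218) were higher as lists. So were cell cycle genes (4 higher of 23, 5 higher and 1 lower adjusted over the list alone, 0.20, 0.0218). Of 21 erythroid genes 2 were lower (1 higher and 5 lower adjusted over the list alone, -0.20, 0.0222). Oxidative phosphorylation (0 higher and 2 lower of 25, 0.0222) had a median of 0.21 that became -0.01 after cyclic loess scaling. After quantile scaling the medians were 0.10 for lectin receptor, 0.26 for STAT3 response, 0.21 for glycolysis and 0.13 for cell cycle genes, and after cyclic loess scaling -0.32 for erythroid genes. The count fell to 977, 774, 749 and 680 without day 1 replicate 1 or 2 or day 4 replicate 6 or 7, and rose to 3243 and 2838 without day 1 replicate 6 or day 4 replicate 5. It was 339 with array spread as a covariate and 3818 with array weights.

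Healthy mice of the initial cohort were compared between days, 4 of day 4 with 8 of day 1, to see what changed without infection. The heat shock genes Hspa1b (2.57 ± 0.38, SE, limma adjusted p = 0.000654) and Hspa1a (1.86 ± 0.32, limma adjusted p = 0.00329) were higher on day 4 in 4 of 4 mice. Clec7a (-1.12 ± 0.19, limma adjusted p = 0.0024) and S100a9 (-0.89 ± 0.15, limma adjusted p = 0.0024), both genes that infection raised, were lower in 4 of 4 mice. In all, 8 genes were higher and 9 lower. Of 28 lists 15 passed between these healthy mice with the preset correlation, B cell, T cell, type I interferon, STAT3 response and lectin receptor genes among those lower, and 0 with an estimated one. Of 14 mature neutrophil genes 2 were lower (1 higher and 8 lower adjusted over the list alone, median -0.65, camera adjusted p = 2.74e-05, adjusted p = 0.305 with an estimated correlation), and of 18 handling genes 2 were higher (3 adjusted over the list alone, 0.00105, adjusted p = 0.305 with an estimated correlation). Of 8 genes of MHC class II presentation 1 was lower (2 adjusted over the list alone, 6.24e-05, adjusted p = 0.305 with an estimated correlation). Leaving out single mice gave 5 to 56 genes. Array spread as a covariate gave 83 genes.

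The validation candida cohort asked whether the response seen in the initial cohort returns in other mice, 18 infected and 2 healthy. Lcn2 was higher by 4.83 ± 0.60 (SE, adjusted p = 0.000168) in 18 of 18 mice, at 10.95 ± 0.86 (SD, n = 18) against 6.17 ± 0.53 (SD, n = 2). Clec4e, the Mincle gene, rose by 3.30 ± 0.30 (adjusted p = 1.3e-05), the chitinase-like gene Chil1 by 3.36 ± 0.55, Vcan by 3.27 ± 0.38, Ifitm1 by 3.22 ± 0.48, Fpr2 by 3.16 ± 0.39 and Steap4 by 3.13 ± 0.49, each in 18 of 18 mice. The inflammatory cytokine gene Il1b (2.33 ± 0.27), the beta-glucan receptor gene Clec7a (1.42 ± 0.28) and S100a8 (1.56 ± 0.17) rose as well. Lower in 18 of 18 mice were the circadian transcription factor gene Dbp (-1.93 ± 0.26, adjusted p = 0.00037), the antigen presentation gene H2-DMb2 (-1.75 ± 0.32), the B cell IgE receptor gene Fcer2a (-1.67 ± 0.36), the antibody chain genes Ighv14-2 (-1.59 ± 0.42) and Igkv6-14 (-1.48), the B cell factor gene Ebf1 (-1.13 ± 0.21) and the cold-inducible gene Cirbp (-1.14). In all, 324 genes rose and 33 fell, 223 and 12 of them at least 2-fold. Vcan probe sets ran from 0.01 to 3.27, those of Steap4 from 1.38 to 3.13 and those of Cebpd from 0.38 to 2.48. Cd79a (-1.29 ± 0.41, adjusted p = 0.117), Cd3e (-0.34), H2-Aa (-0.74), Il17ra (0.84), Ifit1 (0.24) and Arg1 (-1.78) did not pass. Without healthy replicate 2 the count was 5 genes in place of 357.

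Of the lists in the validation cohort 18 passed, 5 of them with an estimated correlation as well. Of 14 mature neutrophil genes 11 rose (12 adjusted over the list alone, median 1.98, camera adjusted p = 1.8e-27, adjusted p = 0.00555 with an estimated correlation) and of 14 immature neutrophil genes 5 (6 adjusted over the list alone, 0.46, 1.9e-06, 0.015). Of 22 Toll-like receptor and interleukin-1 genes 8 rose (13 adjusted over the list alone, 0.73, 2.77e-14, 0.00555), including Tlr2 (1.77) and the adaptor gene Myd88 (1.56). Of 12 STAT3 response genes 6 rose (10 adjusted over the list alone, 1.11, 4.94e-16, 0.00691), including Socs3 (2.76 ± 0.33). Of 15 lectin receptor genes 6 rose (10 adjusted over the list alone, 0.97, 1.53e-15, 0.0288), including Clec4n (1.59 ± 0.23). Of 15 B cell genes 2 fell (10 adjusted over the list alone, -0.96, 1.41e-13, adjusted p = 0.112 with an estimated correlation) and of 8 MHC class II genes 1 (7 adjusted over the list alone, -0.73, 5.64e-08, 0.112). T cell genes were lower as a list with 0 of 17 genes called (-0.43, 1.36e-05, 0.347). Of 13 monocyte genes 2 rose (5 adjusted over the list alone, 0.58, 6.89e-06, 0.112), of 23 type I interferon genes 2 (4 adjusted over the list alone, 0.42, 8.59e-05, 0.347), among them Oas2 (1.36 ± 0.27), and of 17 interferon gamma genes 1 (2 adjusted over the list alone, 0.0358, 0.499). Cell cycle genes were higher as a list (0 of 23, 0.28, 0.00283, 0.386), and ribosomal (0 of 25, -0.17, 0.0162, 0.558) and oxidative phosphorylation genes (0 of 25, -0.18, 0.0127, 0.56) were lower. Glycolysis (1 of 13, 3 adjusted over the list alone, 0.000237, 0.15), oxidant defence (2 of 15, 3 adjusted over the list alone, 0.0137, 0.112), immune suppression (3 of 13, 0.00615, 0.15) and handling genes (4 of 18, 5 adjusted over the list alone, 0.000142, 0.112) were higher. Erythroid (0.7) and platelet genes (0.849) did not pass.

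By day, Lcn2 rose in the validation cohort by 4.81 ± 0.66 (limma adjusted p = 0.0022) in 6 of 6 mice of day 1, by 4.63 ± 0.64 (limma adjusted p = 0.000183) in 8 of 8 of day 2 and by 5.05 ± 0.70 (limma adjusted p = 0.000548) in 4 of 4 of day 3. Clec4e rose by 2.51 ± 0.33, 3.78 ± 0.32 and 3.62 ± 0.35. Csf1r did not pass on day 1 (0.18 ± 0.32, limma adjusted p = 0.999) and rose on day 2 (1.94 ± 0.31, limma adjusted p = 0.000515), when 9 of 13 monocyte genes rose (11 adjusted over the list alone, median 1.41, 5.53e-10, adjusted p = 0.0374 with an estimated correlation). Cd79a fell on day 2 (-1.49 ± 0.43, limma adjusted p = 0.0432) in 8 of 8 mice. MHC class II genes were lower on day 1 as a list, with 8 of 8 adjusted over the list alone and 0 over all genes (-0.82, 1.92e-10, adjusted p = 0.0874 with an estimated correlation). The counts were 30 genes higher and 1 lower on day 1, 725 and 100 on day 2, and 401 and 30 on day 3. The 31 genes of day 1 became 14 without day 1 replicate 3 or 6, 109 without replicate 5, and 16 and 0 without healthy replicate 1 or 2. Without healthy replicate 2, days 2 and 3 gave 128 and 26 genes in place of 825 and 431, and day 3 gave 246 without day 3 replicate 1.

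Across the 12393 genes, the mean effects of days 1 to 3 in the 2 candida cohorts, which shared no mice, had a Pearson r of 0.656 (jackknife SE 0.195 over mice, Spearman rho 0.446); genes are not independent replicates. Of 5951 genes called in the initial cohort over these days, 73.7% had the same sign in the validation cohort, 80.4% of the higher and 68.4% of the lower ones. Genes called in both numbered 317 higher, where 69 would be shared by chance, and 24 lower against 8.8, and 0 were called in opposite directions. A test of the difference between the cohorts called 20 genes, 15 with the larger value in the validation cohort and 5 with the smaller. The dividing-cell gene Mki67 had effects of -1.09 in the initial and 0.45 in the validation cohort (difference 1.54 ± 0.35, adjusted p = 0.0409), the erythroid factor gene Klf1 of -1.44 and 0.11 (1.56 ± 0.34, adjusted p = 0.0409), Ilrun of -2.13 and -0.19, and Wfdc21 of 3.21 and 0.95 (-2.26 ± 0.46, adjusted p = 0.0264). Cirbp, lower in the validation cohort, had effects of 0.32 and -1.14 (limma adjusted p = 0.0409 for the difference), and Dbp of -0.81 and -1.93 (limma adjusted p = 0.0421). Of 21 erythroid genes 1 differed (12 adjusted over the list alone, median 0.90, camera adjusted p = 5.76e-11, adjusted p = 0.365 with an estimated correlation). The count was 0 without validation healthy replicate 2 and 204 without replicate 1, 33 of 60 single mice moved it beyond 1.5 times, and it was 115 after quantile scaling.

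The S. aureus cohort asked how another bloodstream infection changes the same blood transcripts, in 9 infected and 3 healthy mice. Lcn2 was higher by 5.05 ± 0.59 (SE, limma adjusted p = 0.033) in 9 of 9 mice, at 12.44 ± 1.01 (SD, n = 9) against 7.20 ± 0.73 (SD, n = 3). Atp11a (Entrez gene 50770), which encodes a phospholipid flippase, was higher by 2.91 ± 0.33 (limma adjusted p = 0.033) in 9 of 9 mice, and its other probe set gave 0.60. These were the 2 genes called, and 1866 genes had an unadjusted p under 0.05. S100a8 (1.62, limma adjusted p = 0.1), S100a9 (1.70, 0.117), Cd177 (3.86 ± 0.91, 0.123) and Clec4n (1.80, 0.174) did not pass, each higher in 9 of 9 mice, nor did Il1b (0.89), Ifit1 (0.76), Il17ra (0.84), Cd79a (-1.24), Cd3e (-0.66), H2-Aa (-0.93) and Arg1 (-2.64). Clec7a had an effect of 0.19 (limma adjusted p = 0.937). The count was 2477 with array weights, 2002 with array spread and 351 with the liver gene mean as a covariate, 1780 with all 72 mice in the fit and 0 after cyclic loess scaling. It was 768, 98 and 4 without day 2 replicate 2, day 3 replicate 2 or day 3 replicate 1, and 0 without any of the 9 other mice.

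As lists, 21 passed in the S. aureus cohort with the preset correlation and 0 with an estimated one. Of 14 mature neutrophil genes 12 were higher adjusted over the list alone and 0 over all genes (median 2.13, camera adjusted p = 2.09e-11, adjusted p = 0.247 with an estimated correlation), and of 14 immature neutrophil genes 9 and 1 (2.82, 1.08e-08, 0.28). Of 12 STAT3 response genes 11 were higher adjusted over the list alone (1.33, 3.2e-11, adjusted p = 0.247 with an estimated correlation), of 23 type I interferon genes 15 (0.92, 1.21e-10, 0.247), of 13 glycolysis genes 7 (0.70, 3.23e-06, 0.247), of 23 cell cycle genes 11 (0.67, 1.06e-06, 0.361) and of 17 interferon gamma genes 6 (0.287 with an estimated correlation), each with 0 over all genes. Of 8 MHC class II genes 6 were lower adjusted over the list alone (-0.99, 1.01e-05, 0.287), and B cell (-1.24, 1.13e-07, adjusted p = 0.304 with an estimated correlation) and T cell genes (-0.70, 3.23e-06, 0.361) were lower as lists. With the liver gene mean as a covariate, oxidative phosphorylation turned from -0.28 (0.000629, 0.525) to 0.27 (0.0406), cell cycle genes from 0.67 to -0.07, and natural killer (0.80, 0.00212, 0.525) and platelet genes (0.63, 0.0392, 0.618) to -0.41 and -0.38.

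Each day of S. aureus infection was compared with the 3 healthy mice, with 2 infected mice on day 1; days were not tested against each other. Ifi44l (3.31 ± 0.46, limma adjusted p = 0.0353), the chemokine gene Cxcl10 (3.04 ± 0.43, 0.0353), the nucleic acid sensor gene Zbp1 (2.52 ± 0.28, 0.0181), Usp18 (1.97 ± 0.31, 0.0466) and Dhx58 (1.89 ± 0.24, 0.0269) were higher in 2 of 2 mice, and these genes were chosen after their values were seen. Of 23 type I interferon genes 19 were higher adjusted over the list alone and 3 over all genes (median 1.58, 1.7e-13, adjusted p = 0.225 with an estimated correlation), of 17 interferon gamma genes 13 and 0 (1.53, 1.66e-09, 0.225), and of 23 cell cycle genes 17 and 0 (1.44, 3.27e-10, adjusted p = 0.397 with an estimated correlation). The mean signal of the 4 liver genes differed as well, at 6.31 ± 2.04 (SD, n = 2) on day 1, 11.36 ± 1.72 (SD, n = 5) on day 2 and 7.72 ± 3.82 (SD, n = 2) on day 3 against 12.53 ± 1.19 (SD, n = 3) in healthy mice; with it as a covariate the day 1 medians were 1.16, 1.17 and 0.31, the cell cycle list no longer passed (camera adjusted p = 0.31), and 12 of the 29 genes of day 1 were among the 173 called. On day 2, 14 of 15 B cell genes (-1.99, 3.71e-13, 0.193), 8 of 8 MHC class II genes (-1.49, 6.19e-10, 0.193) and 16 of 25 ribosomal genes (-0.44, 5.06e-13, adjusted p = 0.193 with an estimated correlation) were lower adjusted over the list alone, and Lcn2 (5.61 ± 0.63, limma adjusted p = 0.0234) and Atp11a (3.27 ± 0.35, limma adjusted p = 0.0234) were higher in 5 of 5 mice. On day 3, 13 of 14 mature neutrophil genes were higher adjusted over the list alone (2.35, adjusted p = 0.482 with an estimated correlation). limma called 29 genes on day 1 (29 higher), 2 on day 2 and 0 on day 3, with 2161, 1408 and 1231 at an unadjusted p under 0.05. Leaving out single mice gave 0 to 772 genes on day 1, 0 to 251 on day 2 and 0 to 42 on day 3, with the highest value each time without day 2 replicate 2. Day 1 gave 60, 48 and 51 without day 2 replicate 3, 4 or 5 and 2 without healthy replicate 3, day 2 gave 14 without either day 3 mouse, and day 3 gave 1 without day 3 replicate 2. Across genes the effects had a Pearson r of 0.625 with those of the initial candida cohort (jackknife SE 0.151, Spearman rho 0.591), where 80.1% of 5951 genes had the same sign, and of 0.797 with those of the validation cohort, where 356 of 357 called genes had the same sign. With the liver gene mean as a covariate the values of r were 0.661 and 0.663. That between the candida cohorts, 0.656 without the covariate, was then 0.704, so the order of these agreements depended on the liver genes.

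Which transcripts separate candidiasis from S. aureus infection was asked by the difference of their effects, each against the healthy mice of its cohort, over days 1 to 3. Each pathogen was given in its own cohort. The female transcript Xist exceeded a signal of 8 in 11 of 12 mice of the S. aureus cohort and in 0 of 60 candida cohort mice. The pathogen can therefore not be told apart from other differences between the cohorts, such as sex, that change the response to infection. Of 14 immature neutrophil genes 4 had lower effects in candidiasis, Ngp, Ltf and Camp among them (adjusted p = 0.294 for the list with an estimated correlation), whereas Lcn2 (-1.16, adjusted p = 0.324) and Mmp8 (-1.46, adjusted p = 0.239) of the same list did not pass. Ngp (difference -3.44 ± 0.79, SE, adjusted p = 0.0136) had effects of 2.15, 1.83 and 5.52 in the initial, validation and S. aureus cohorts, the iron-binding lactoferrin gene Ltf (-3.42 ± 0.80, 0.0153) of 0.96, 0.24 and 4.23, and the cathelicidin gene Camp (-2.73 ± 0.73, 0.0376) of 0.80, 0.41 and 3.45. The metabolic enzyme genes Hao2 (5.17 ± 0.58, 7.95e-09), Sult2a2 (4.76 ± 0.76) and Cyp2b9 (4.15 ± 0.57), which liver expresses, had effects of -5.28, -4.76 and -4.14 in the S. aureus cohort and of -0.11, -0.02 and -0.01 in the initial candida cohort. Their signals in healthy mice were 7.58, 11.28 and 8.93 in the S. aureus cohort, 2.13, 4.30 and 3.96 in the initial and 2.48, 4.52 and 4.06 in the validation cohort. With signals that low in healthy mice, a fall of that size could not have been seen in the candida cohorts. Acaa1b (4.45), Gsta2 (4.37), the glucose transporter gene Slc2a2 (4.12), Hamp2 (4.08, other probe set -0.09), Cyp2c50 (3.97), Serpina6 (3.87) and Ces1g (3.85) followed. In all, 81 genes had a higher and 68 a lower effect in candidiasis, of which 48 and 28 were kept with the liver gene mean as a covariate. The lower ones included the lipase gene Lipg (-3.24, probe sets from -3.24 to -0.39), the chemokine-like gene Prok2 (-2.65), Spon1 (-2.07 ± 0.35), the interferon gene Oasl2 (-1.52 ± 0.39), Ugt8a (-1.52, other probe set 0.14), the cell division gene Cdca5 (-1.56) and the nucleotide synthesis gene Rrm2 (-1.54 ± 0.36). Clec7a (1.41 ± 0.40, adjusted p = 0.0567) and Ifit1 (-1.17, 0.0837) did not pass. Comparing the infected mice directly, with no cohort term, turned the direction of Hao2 (-0.14), Sult2a2 (-2.10), Acaa1b (-0.04), Cyp2b9 (-0.77), Slc2a2 (-0.19), Hamp2 (-0.45) and Ces1g (-0.12). The count of 149 was 83 with the liver gene mean as a covariate, 356 with the initial and 0 with the validation candida cohort alone, and 21, 721, 66, 383 and 263 without S. aureus cohort healthy replicate 3 or 1, S. aureus day 1 replicate 1, day 2 replicate 2 or validation healthy replicate 2.

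Of the lists 10 passed for this difference with the preset correlation and 0 with an estimated one. Of 23 cell cycle genes 8 were lower in candidiasis (16 adjusted over the list alone, median -0.72, camera adjusted p = 8.06e-17, adjusted p = 0.0678 with an estimated correlation), including Top2a (-1.23 ± 0.34) and Birc5 (-1.30 ± 0.36). Of 14 immature neutrophil genes 4 were lower (5 adjusted over the list alone, -1.12, 3.84e-05, 0.294), of 23 type I interferon genes 1 (10 adjusted over the list alone, -0.53, 6.44e-07, 0.294), of 15 natural killer genes 1, the chemokine gene Xcl1 (-0.96 ± 0.24; 5 adjusted over the list alone, -0.77, 6.44e-07, 0.414) and of 17 interferon gamma genes 1, the inhibitor gene Socs1 (-1.0 ± 0.22; -0.32, 0.0146, adjusted p = 0.663 with an estimated correlation). Cytokine genes were lower as a list (0 of 15, 2 adjusted over the list alone, -0.27, 0.0141, 0.273). Of 15 B cell genes 1 was higher, Fcer2a (1.67 ± 0.45; 2 adjusted over the list alone, 0.55, 3.74e-06, 0.414). MHC class II (0 of 8, 5 adjusted over the list alone, 0.69, 1.05e-05, 0.322), oxidative phosphorylation (0.40, 6.44e-07, 0.414) and ribosomal genes (0.17, 0.0469, 0.878) were higher as lists.

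On day 2 alone, 652 genes had a higher and 212 a lower effect in candidiasis, with pathogen and cohort again not told apart. The genes named here were chosen after their values were seen. The antigen presentation gene H2-Aa (difference 1.39 ± 0.32, SE, adjusted p = 0.00555) had effects of -0.12, -0.44 and -1.49 in the initial, validation and S. aureus cohorts, Csf1r (1.79 ± 0.34, 0.00125) of 2.73, 1.94 and 0.80, and the fungal receptor gene Clec7a (1.77 ± 0.44, 0.0101) of 1.75, 1.54 and -0.05. The acute-phase gene Saa2 (-5.77 ± 1.85, 0.0441) had effects of 0.36, 3.89 and 6.90, and the neutrophil chemokine gene Cxcl1 (-4.21 ± 1.31, 0.0382) of -0.29, 0.93 and 4.07. Of 15 B cell genes 10 were higher in candidiasis (14 adjusted over the list alone, median 1.36, 6.79e-10, adjusted p = 0.294 with an estimated correlation), of 8 MHC class II genes 7 (8 adjusted over the list alone, 1.40, 4.66e-09, 0.294), of 25 ribosomal genes 10 (21 adjusted over the list alone, 0.55, 1.15e-10, 0.294) and of 13 monocyte genes 6 (8 adjusted over the list alone, 1.2, 3.93e-05, 0.294). Of 15 lectin receptor genes 4 were higher (8 adjusted over the list alone, 0.83, 2.23e-05, 0.442). The count of 864 was 427 and 503 without S. aureus cohort healthy replicate 1 or 3, 1662 with the initial and 0 with the validation candida cohort alone.

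A score asked whether the initial cohort's genes tell infected from healthy mice elsewhere: the mean signal of its 50 leading higher genes minus that of its 50 leading lower genes. In the validation cohort the score was 0.77 ± 0.87 (SD, n = 18) with candida and -1.19 ± 0.12 (SD, n = 2) without, a difference of 1.96 (exact permutation p = 0.0105, smallest possible 0.00526). The area under the receiver operating curve was 0.972. The lowest infected mouse, of day 1, lay at -1.22, and the day 1 mice at -0.12 ± 0.75 (SD, n = 6). In the S. aureus cohort the score was 1.81 ± 0.90 (SD, n = 9) against -0.91 ± 0.39 (SD, n = 3), a difference of 2.71 (exact permutation p = 0.00455, the smallest possible) with an area of 1, so that it was also high in the bacterial infection. Without validation healthy replicate 1 the difference was 1.88 (exact permutation p = 0.105) and without replicate 2 it was 2.04 (exact permutation p = 0.0526, the smallest that 19 arrangements allow).

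**Figure D3:**
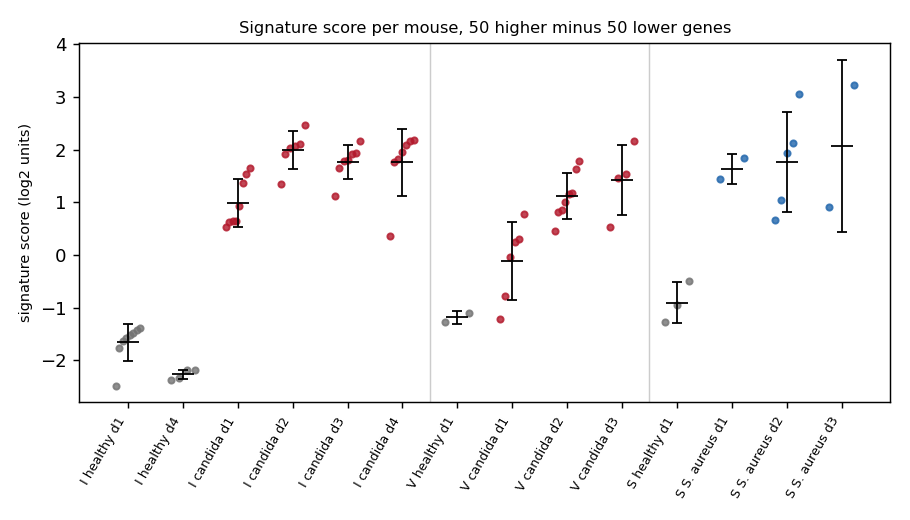
Signature score in log2 units, the mean of 50 higher minus that of 50 lower genes chosen in the initial cohort, for each of the 72 mice by group (I initial, V validation and S S. aureus cohort), with bars for the mean ± SD and points in order of value within a group. Infected mice of the S. aureus cohort lay at 1.81 ± 0.90 and its healthy mice at -0.91 ± 0.39.

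Levels of liver transcripts varied between blood samples. Alb (Entrez gene 11657), the albumin gene of hepatocytes, exceeded a signal of 8 in 40 of 72 mice, in 6 of 28 infected and 7 of 12 healthy mice of the initial cohort, 15 of 18 and 2 of 2 of the validation cohort, and 7 of 9 and 3 of 3 of the S. aureus cohort. The mean of Alb, Apoa1, Apoa2 and Ttr was 6.32 ± 1.65 (SD, n = 28) in infected and 7.90 ± 2.21 (SD, n = 12) in healthy mice of the initial cohort, a difference of -1.58 (permutation p = 0.0161). All these infected mice were of title number set A, whose healthy mice lay at 6.83 ± 1.63 (SD, n = 5). In the validation cohort the mean of the liver genes was 10.11 ± 2.43 (SD, n = 18) against 12.09 ± 1.56 (SD, n = 2, exact permutation p = 0.295) and in the S. aureus cohort 9.43 ± 3.05 (SD, n = 9) against 12.53 ± 1.19 (SD, n = 3, exact permutation p = 0.123). Xist (Entrez gene 213742), the transcript that silences an X chromosome in females, lay between 9.99 and 11.12 in 11 of the 12 mice of the S. aureus cohort and at most at 5.24 in the 60 mice of the candida cohorts, whereas the labels call the mice male. The exception was S. aureus day 2 replicate 1, with Xist at 4.14 and the Y-linked Eif2s3y at 6.74.

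**Figure D4:**
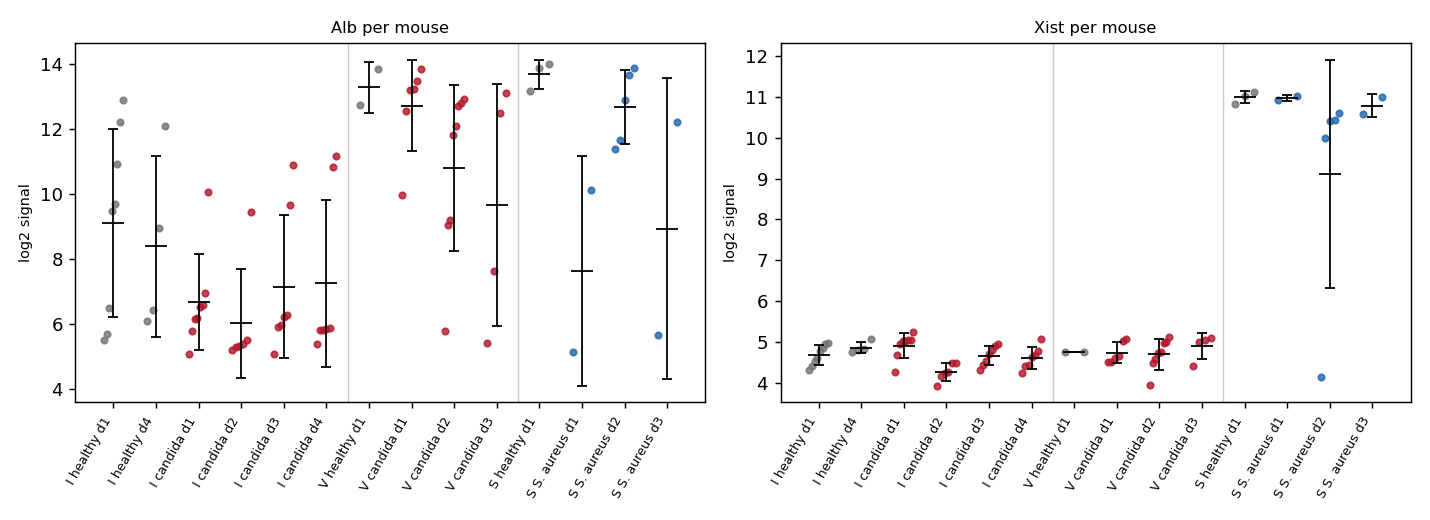
Log2 signal of the hepatocyte gene Alb and of Xist in each of the 72 mice by group (I initial, V validation and S S. aureus cohort), with bars for the mean ± SD and points in order of value within a group. Alb exceeded 8 in 40 mice, and Xist lay between 9.99 and 11.12 in 11 of 12 mice of the S. aureus cohort.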

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

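Of the tests below, those of held-out hepatocyte genes, of release by infection, of lower genes against liver RNA, of genes higher in candida minus S. aureus against liver RNA, of mixed RNA, of Y-linked genes and of array spread were chosen only after the result was seen; the splits of the mice, the tests of sex-biased liver genes and the test of the number of mice were written beforehand.

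Effects of the infections differed between cohorts for 149 genes in candida minus S. aureus over days 1 to 3 and for 864 on day 2, and effects of candidiasis differed for 20 genes between the validation and the initial cohort. The genes with the largest such differences by the naming rule were Hao2 (5.17), Sult2a2 (4.76), Acaa1b (4.45), Gsta2 (4.37), Cyp2b9 (4.15), Slc2a2 (4.12), Hamp2 (4.08), Cyp2c50 (3.97), Serpina6 (3.87) and Ces1g (3.85), liver genes higher in the difference. On the other side were Ngp (-3.44), Ltf (-3.42), Lipg (-3.24), Camp (-2.73), Prok2 (-2.65), Spon1 (-2.07), Cdca5 (-1.56), Rrm2 (-1.54), Ugt8a (-1.52) and Oasl2 (-1.52). Probe sets outside the gene table moved too in candida mice of the initial cohort: 322 of 691 with several symbols (167 higher, 155 lower) and 662 of 1555 with no symbol (199 higher, 463 lower).

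Single mice lay apart from the others of their group. By signature score these were healthy day 1 replicate 3 of the initial cohort, at -2.49 with the nearest at -1.77, and candida day 4 replicate 2 of the initial cohort, at 0.36 with the nearest at 1.76. By Alb they were initial candida day 1 replicate 4 (10.05, nearest 6.94), initial candida day 2 replicate 5 (9.45, nearest 5.5) and validation candida day 1 replicate 6 (9.98, nearest 12.57). By Xist they were validation candida day 3 replicate 3 (4.41, nearest 5) and S. aureus day 2 replicate 1 (4.14, nearest 9.99), and by Eif2s3y initial candida day 4 replicate 4 (3.61, nearest 6.33) and S. aureus day 2 replicate 1 (6.74, nearest 2.4). Chance flags about 1 in 20 groups, which is 2.5 of the 50 groups tested here, against 9 found.

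Liver transcripts varied between blood libraries of all 3 cohorts. A liver source may explain this, since all 21 measured members of a held-out list of 23 hepatocyte genes rose with the liver score among the 12 healthy mice of the initial cohort (median slope 0.781), where 250 genes rose with the score and 0 fell; Alb reached 13.69 on average in the healthy mice of the S. aureus cohort. Release of liver RNA by infection cannot be the whole cause in the initial cohort, because Alb exceeded 8 in 7 of its 12 healthy mice. Its infected mice, all of title set A, had a score of 6.32, below healthy ones (difference -1.58, permutation p = 0.0161). Healthy mice lay at 6.83 ± 1.63 (SD, n = 5) in set A and 8.66 ± 2.35 (SD, n = 7) in set B. Within set A the gap was inside the SD and untested, so set B raised the difference. Liver RNA as the whole cause of genes lower in candida mice is excluded, since 74.1% of the lower calls (2690 of 3628) were kept with the score as a covariate. In candida minus S. aureus 59.3% (48 of 81) of higher and 41.2% (28 of 68) of lower calls were kept. Liver RNA can therefore not be told apart from infection. The score, at 9.43 in infected and 12.53 in healthy mice of the S. aureus cohort, overlaps with infection there. How the RNA entered the samples was not tested.

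A female transcript pattern in the S. aureus cohort stood against labels of male mice. Mixed male and female RNA as its cause is excluded, since 0 libraries of that cohort had high Xist with high Eif2s3y. Female mice under a male label may explain it: in 11 of the 11 mice with high Xist the mean of Kdm5d and Uty, the other measured Y-linked genes, lay between 2.60 and 3.21, below the lowest of the 60 candida cohort mice (4.08), against 4.58 in S. aureus day 2 replicate 1, of low Xist. In all 3 healthy mice of that cohort 4 of 9 measured male-biased liver genes lay below both healthy validation mice. Of 4 female-biased ones 2 lay above (chance 10 percent per gene). This did not decide, but means lay on the female side, as for Cyp4a12a (2.64 against 6.46), except for Ugt2b38 and Sult3a1. Sex and infection stay open as untested sources of liver genes in candida minus S. aureus. Hao2 was at 7.58 against 2.48 in these healthy mice and 2.61 in S. aureus infected ones.

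Few genes were called in the S. aureus cohort, 2 in the mean of its days. In the initial cohort such numbers of mice sufficed: 100 draws of its candida mice in the same numbers gave 694 to 7231 calls and 0 draws gave as few. The draws cannot exclude the number of mice as a cause at the spread of the S. aureus cohort. There the liver score varied more, with an SD of 3.05 in infected mice against 1.65 in those of the initial cohort. Array spread may contribute, as 2002 genes were called with it as a covariate, and the cohort's spread was 3.46 ± 0.12 (SD, n = 9) in infected and 3.36 ± 0.02 (SD, n = 3) in healthy mice. That reading is not unique, because array weights gave 2477, the fit on all 72 mice 1780 and liver score as a covariate 351, and array spread gave 0 on day 2 alone. Effects were not smaller in the signature difference (2.71 against 1.96 in the validation cohort), the median residual SD was 0.298 against 0.273 in the initial and 0.262 in the validation cohort, and whether the response varied more between mice stays open as untested.

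Chance was weighed by counting how often other splits of the mice called as many genes, 100 splits unless given, the real one counted. No other split came near the real count for the initial cohort's day 2 (1 split, 8195 genes against at most 3649) or day 3 (1, 4464 against 371). The same held for its day 4 (1, 4337 against 2165) and any difference among days (1, 6122 against 20). These counts argue against chance, though 100 splits can show no share under 1 in 100. Few splits, but not only the real one, did so for the initial cohort's lists (2 splits, 18 against 18), its day 1 (2, 1943 against 3586), its day 4 against day 1 (4, 1553 against 2987) and the S. aureus mean (4, 2 against 1506). The S. aureus lists (1, 21 against 20) stood only narrowly above the other splits. With no adjustment for the number of results weighed, chance is not excluded for these. It could not be excluded for healthy day 4 against day 1 (12 splits, 17 genes against 682), the lists of day 4 against day 1 (44, 8 against 18), S. aureus day 2 (6 of 56 splits, 2 genes against 1168), candida minus S. aureus (17, 149 against 2574), its lists (65, 10 against 20) and its day 2 (5, 864 against 1602). Splits with several times the real count, as for the healthy mice, the S. aureus mean, S. aureus day 2 and candida minus S. aureus, point to a structure of the samples other than the groups.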

How the results depend on the processing

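Tests with liver score or array spread as a covariate, those that leave out mice with Alb above 8 or a mouse with low Xist, and the fit of the initial cohort with healthy mice of each day as a group (6 groups), were chosen only after the results were seen; the others were planned. Of called results, genes kept direction and side of the threshold in 2565 cases, stayed in direction but lost the call in 214 and turned in 12; gene lists did so in 187, 108 and 5. Of counts, agreements and scores under alternatives, 163 stayed within 1.5 times the reported value or within its error and 100 moved further. Except where said, the cause was not tested. Quantile scaling gave 5319 genes for initial day 2, 97 for healthy day 4 against day 1, 900 for candida day 4 against day 1, 3534 for any difference among days, 98 for candida minus S. aureus (412 on day 2), 115 for validation minus initial cohort, and S100a9 at -0.06 in candida minus S. aureus. Cyclic loess scaling gave 77 for the healthy mice, 1.0e+03 for day 4 against day 1, 79 for validation day 1, 0 for the S. aureus mean, 6 and 0 for its days 1 and 2, and 64 between the candida cohorts. The share of higher calls was 52.2% after loess against 42.1% as deposited on initial day 2, where the median of all genes moved from -0.13 to -0.03, 32.5% against 47.1% in the healthy mice, and 74.3% (loess) and 67.3% (quantile) against 54.4% for candida minus S. aureus. The mean of all probe sets gave 34 between candida cohorts. Leaving out genes of lower signal, by construction fewer genes tested, gave 3802 for the initial mean, 4104 on day 2, 10 for healthy mice, 729 for day 4 against day 1, 3581 for any difference, 6 and 7 on S. aureus days 1 and 2, 22 for candida minus S. aureus and 59 between cohorts. Array weights gave 1.4e+03 for healthy mice, 3818 for day 4 against day 1, 9449 for any difference, 2477 for the S. aureus mean, 3083, 646 and 587 on its days, 1550 for candida minus S. aureus (2477 on day 2; Il17ra -0.080, S100a9 -0.076) and 1 between cohorts. The fit on all 72 mice gave 9 for healthy mice, 1780 for the S. aureus mean and 2077, 1.0e+03 and 832 on its days. Candida minus S. aureus was 6923 (3548 on day 2) with no cohort term, 356 (1662) with the initial and 0 (0) with the validation candida cohort. No cohort term turned Hao2 (-0.14), Sult2a2 (-2.10), Acaa1b (-0.041), Cyp2b9 (-0.77), Slc2a2 (-0.19), Hamp2 (-0.45), Ces1g (-0.12), Ccna2 (0.044), S100a9 (-0.11), Arg1 (-1.21), Cd3e (0.19) and H2-Aa (-0.089), and the validation cohort alone turned Clec4n (-0.21), Cd79a (-0.054) and Cd3e (0.32). Title set A alone and title set as a block gave Arg1 0.41 and 0.41 in the initial cohort. With an estimated correlation the passing lists were 6, 5, 0, 0 and 0 in the initial cohort, the validation cohort, the S. aureus cohort, candida minus S. aureus and day 4 against day 1, and fry gave 5, 4 and 0 in the last 3. Lists that did not pass turned with fry, at an adjusted p of 0.864 for dendritic cell genes in the initial, 0.977 for platelet genes in the validation and 0.825 and 0.79 for plasma cell and interleukin-17 genes in the S. aureus cohort, 0.986 for platelet, dendritic cell and complement genes in candida minus S. aureus, and 0.996 and 0.951 for tissue and type I interferon genes in day 4 against day 1. With the mean of all probe sets, platelet genes in candida minus S. aureus (0.958) and type I interferon genes in day 4 against day 1 (0.983) did. With liver score as a covariate, dendritic cell genes in the initial (0.868), tissue genes in the validation (0.409), plasma cell and immune suppression genes in the S. aureus cohort (0.733 and 0.814), eosinophil, complement, tissue and immune suppression genes in candida minus S. aureus (0.971, 0.971, 0.249 and 0.917) and tissue genes in day 4 against day 1 (0.979) did. The Spearman rho between candida cohorts was 0.446. Liver score as a covariate gave 31 for healthy mice, 284 on validation day 3, 351 for the S. aureus mean, 173, 287 and 74 on its days, 83 for candida minus S. aureus and 35 between cohorts. It turned Apoa2 (0.12) and Arg1 (0.46) in the initial cohort, Arg1 (0.18) in the validation cohort, Clec7a (-0.92) and Arg1 (1.79) in the S. aureus cohort, Arg1 (-0.19) and Cd3e (0.08) in candida minus S. aureus, and of passing lists, all in the S. aureus cohort, oxidative phosphorylation (adjusted p = 0.0406 upward), natural killer (0.369), platelet (0.813), cell cycle (0.813) and tissue genes (0.672); Apoa2 is part of the score, so its turn follows from the construction. Array spread as a covariate gave 4012 for the initial mean, 3129 and 2609 on days 1 and 2, 83 for healthy mice, 339 for day 4 against day 1, 1838 for any difference, 48 on validation day 1, 2002 for the S. aureus mean, 2230, 0 and 1385 on its days, 225 for candida minus S. aureus (282 on day 2) and 44 between cohorts, with Tnnt3 at 0.008 in the initial cohort. Both covariates gave 3963, 2979, 2655, 92, 375 and 1843 for the same first 6 results, 76, 402 and 283 on validation days 1, 2 and 3, 418 for the S. aureus mean, 145, 904 and 198 on its days, 300 for candida minus S. aureus on day 2 and 60 between cohorts. They turned Apoa2 (0.071) in the initial, Arg1 (0.10) and Ifit1 (-0.018) in the validation and Arg1 (1.69) in the S. aureus cohort, and Arg1 (-0.35) and Cd3e (0.071) in candida minus S. aureus. Without mice of Alb above 8, so with fewer mice, the initial mean was 3371 and days 1, 3 and 4 were 1196, 2417 and 2466, with Acaa1b at 0.035 and Arg1 at 0.31. Liver score with the low-Xist mouse left out gave 247 for the S. aureus mean, 86, 158 and 31 on its days and 74 for candida minus S. aureus, with Clec7a (-0.74) and Arg1 (1.79) turned in the S. aureus cohort and Arg1 (-0.21) and Cd3e (0.08) in the difference. Leaving out each mouse gave 5655 to 7260 for the initial mean, 1662 to 2200, 7423 to 8511, 3766 to 5034 and 3450 to 5335 on its days, and 4935 to 7358 for any difference. Healthy mice ranged from 5 to 56, with 11, 5, 46, 31 and 9 without healthy day 1 replicate 1, 2, 3, 4 or 5, 28, 41 and 11 without healthy day 4 replicate 1, 2 or 3, 56 without candida day 1 replicate 2 and 26 without candida day 3 replicate 2. Day 4 against day 1 ranged from 680 to 3243, with 977, 774 and 3243 without day 1 replicate 1, 2 or 6 and 2838, 749 and 680 without day 4 replicate 5, 6 or 7. The validation mean ranged from 5 (without healthy replicate 2) to 440. Its day 1 ranged from 0 to 109, with 14, 109 and 14 without day 1 replicate 3, 5 or 6 and 16 and 0 without healthy replicate 1 or 2. Its day 2 ranged from 128 (without healthy replicate 2) to 978 and its day 3 from 26 (the same mouse) to 536, with 246 without day 3 replicate 1. The S. aureus mean ranged from 0 to 768, with 768 without day 2 replicate 2, 4 and 98 without day 3 replicate 1 or 2 and 0 without any of the 9 others. Its day 1 ranged from 0 to 772, with 772, 60, 48 and 51 without day 2 replicate 2, 3, 4 or 5, 2 without healthy replicate 3, 35 without either day 3 mouse, which is within 1.5 times, and 0 without the others; day 2 ranged from 0 to 251, with 251 without day 2 replicate 2, 14 without either day 3 mouse and 0 without the others; and day 3 ranged from 0 to 42, with 42 without day 2 replicate 2 and 1 without day 3 replicate 2. Candida minus S. aureus ranged from 21 to 721, with 21 and 721 without S. aureus cohort healthy replicate 3 or 1, 66 and 383 without S. aureus day 1 replicate 1 or day 2 replicate 2 and 263 without validation healthy replicate 2, and on day 2 from 427 to 1277, with 427 and 503 without S. aureus cohort healthy replicate 1 or 3. Validation minus initial ranged from 0 to 204, moving beyond 1.5 times without 33 of 60 mice, with 0 and 204 without validation healthy replicate 2 or 1. Agreement ranged from 0.521 to 0.693 between candida cohorts and from 0.526 to 0.669 with S. aureus, and the signature difference from 1.88 to 2.08 (validation; exact permutation p = 0.105 and 0.0526 without healthy replicate 1 or 2, where 19 arrangements allow no p under 0.0526) and from 2.53 to 2.92 (S. aureus). No paired analysis was possible because replicate numbers only follow the order of the arrays and pair no mice. Signal over background was not given per probe set in the values used here, so what dim genes limit was seen only by leaving out genes of lower signal.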

Other observations

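The test of the acute phase hypothesis, its control and leaving out mice with Alb above 8 were chosen only after the liver transcripts had been seen; the gene lists and their tests were planned.

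Gene groups were called on different days, which does not show that the days differ. In the initial cohort, platelet genes passed as a list on days 3 and 4 with the preset correlation only (adjusted p = 0.355 and 0.454 with an estimated correlation). Vwf, the clotting adhesion gene, rose by 2.14 ± 0.58 (limma adjusted p = 0.0038) and Treml1, a platelet granule receptor gene, by 1.85 ± 0.42 (limma adjusted p = 5e-04) in the 7 mice of day 3. Without the mice of Alb above 8, 10 and 4 of 13 platelet genes were called on days 3 and 4, and Vwf had an effect of 0.38 (adjusted p = 0.296) in the mean of days. B cell genes fell on the same days, with 13 of 15 lower on each (adjusted p = 0.221 and 0.316 with an estimated correlation). Type I interferon and cell cycle genes had medians of 1.58 and 1.44 on day 1 of S. aureus infection, in 2 mice, with 3 and 0 of 23 genes called over all genes, and the lists did not pass with an estimated correlation (adjusted p = 0.225 and 0.397). The liver score was 6.31 in these mice against 12.53 in healthy ones, and with it as a covariate the medians were 1.16 and 0.31 on day 1 and the cell cycle median over the days of that cohort went from 0.67 to -0.07. B cell, MHC class II and ribosomal genes had medians of -1.99, -1.49 and -0.44 on day 2, with 0 genes called by limma over all genes and an adjusted p of 0.193 for each list with an estimated correlation; 1408 genes had an unadjusted p under 0.05 on that day. Type I interferon genes also passed as a list on days 2 and 3 of S. aureus infection (medians 0.64 and 0.51, adjusted p = 0.193 and 0.781 with an estimated correlation). Whether days differ in the S. aureus cohort was not tested, and for day 4 against day 1 in the initial cohort the platelet list passed with the preset correlation only (median 0.72, camera adjusted p = 0.0218, adjusted p = 0.704 with an estimated correlation).

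In both candida cohorts the most monocyte genes were called on day 2, 13 of 13 in the initial cohort and 9 of 13 in the validation cohort, against 0 and 2 on days 1 and 3 of the latter, whose days were not tested against each other. The class II gene H2-DMb2 was lower by 0.47 log2 units in the initial cohort, and its effect in the validation cohort was -1.75. As lists, monocyte, MHC class II and B cell genes had lower effects in the validation than in the initial cohort over days 1 to 3 (medians -0.58, -0.59 and -0.52, camera adjusted p = 5.28e-05, 7.96e-06 and 7.42e-06, adjusted p = 0.365, 0.365 and 0.491 with an estimated correlation). For this difference 11 of 28 lists passed with the preset correlation, lectin receptor genes among them (median -0.22, camera adjusted p = 0.0254, adjusted p = 0.72 with an estimated correlation), and 0 with an estimated one.

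A hypothesis was that liver RNA in blood of infected mice carries an acute phase state of the liver. It was tested by whether acute phase genes rise more steeply with the liver score in the 28 candida than in the 12 healthy mice of the initial cohort. Of 18 listed genes 17 were measured, and 15 rose more steeply, adjusted over the list alone, with Saa1 at a slope of 0.36 in healthy and 1.72 in candida mice, Saa2 at 0.12 and 1.33 (adjusted p = 5.19e-17 for the difference) and Orm2 at 0.10 and 1.09. Mbl2 rose less steeply (slope difference -0.15, adjusted p = 0.0195) and Hamp did not pass (0.09, adjusted p = 0.149). Among 18 other hepatocyte genes 4 were steeper and 2 less steep, with a median slope difference of 0.08 against 0.70 for the acute phase genes. The result is consistent with the hypothesis, and samples of liver, which would test it directly, were not analysed here.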
